A study of Mus musculus with 32 samples.

How the data were processed

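Primary chondrocytes had been isolated from the femoral heads of LG/J and SM/J mice of both sexes at postnatal day 21, plated at 100000 cells per well, grown in medium with 10% serum and harvested unpassaged after 4 days, per the labels. Libraries were made from total RNA with a SMARTer kit, per the labels' protocols. The title of each sample gives strain, sex and a number from 1 to 8, and strain and sex defined 4 groups of 8 libraries. The labels do not say whether libraries with different numbers came from separate animals or cultures.

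Reads had been aligned to GRCm38 with STAR 2.0.4b and counted per gene with featureCounts 1.45 from the Subread package, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table per library with whole-number read counts for 41388 Ensembl genes, next to CPM and RPKM. The deposited CPM values equalled the count divided by the library total, with a largest difference of 1.2e-10 CPM. The deposited RPKM values equalled that CPM divided by the gene length in the table, with a largest difference of 9.1e-11 RPKM. Every test below used the deposited counts, and no column belonged to a sample of another study. A symbol was found for 40254 of the IDs in a table of gene names, and the 1134 unmatched IDs held 0.109% of all counts. Positions are those of the deposited tables, on GRCm38. Of the IDs, 40340 were found in a GENCODE annotation of GRCm38, used for biotypes and transcripts, and 40281 of these overlapped the annotated gene on the same chromosome.

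Total counts per library ran from 15840330 to 25571598, and 21214 to 26789 genes had at least 1 read. Genes with few reads were removed with filterByExpr, which kept 16136 genes. Counts were scaled with TMM and fitted in R 4.3.3 with the quasi-likelihood model of edgeR 4.0.16, with robust dispersions, 1 mean per group and all 32 libraries in 1 fit. The contrasts were LG/J minus SM/J over both sexes, in females and in males, male minus female in each strain and over both strains, and the difference of the strain contrasts between sexes. P-values were adjusted by Benjamini and Hochberg over the genes kept, and a gene was called at an adjusted p under 0.05. A log2 fold change is the estimate of that fit and is given ± its standard error (SE), taken as its size over the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± standard deviation (SD), unless stated otherwise.

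The tests were tried on simulated counts drawn from the means and library sizes of these data, with 100 genes changed by 1.5-fold and 100 by 2-fold among 16136. In a simulated strain comparison over both sexes, 58% of the 1.5-fold and 80% of the 2-fold changes were recovered, and 8 of 146 calls (5.48%) were false. In a simulated sex comparison within SM/J, 29% and 63% were recovered and 4 of 96 calls (4.17%) were false. Each simulated library was drawn independently of the others. The simulation held no libraries standing apart from their group, no pairs closer than the rest and none with transcripts of both sexes. The real data hold such libraries, so these rates may not apply to them.

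Before the data were examined, 45 gene lists were fixed, covering cartilage genes, signalling and metabolic pathways, immune genes, markers of other cell types, signs of RNA quality and sex-linked genes. The 42 lists with at least 5 genes kept were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with all other genes, and p-values were adjusted over these lists. Camera with a correlation estimated per list, and fry, which asks whether the members of a list move 1 way on balance, were run beside it. Where a camera result is given as an adjusted p with an estimated correlation, the second form was used.

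The rule for naming genes was also set before the data were examined. It took the 10 largest strain differences each way among genes called over both sexes and in each sex, with a mean log2 CPM of at least 3 and no overlap between the 16 libraries of each strain, leaving out names of predicted genes and pseudogenes. Of 258 genes that met these criteria, 37 had such names and 221 were left. It added 13 cartilage, Wnt, DNA repair and cell cycle genes given whatever their result, up to 3 members of each list with the smallest p among those called, the 5 largest autosomal sex differences each way with a mean log2 CPM of at least 1, the sex-linked lists, and the genes called for a strain difference that differed between sexes. Other genes named below were chosen after their values were seen.

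Alternatives set before the data were examined were other scalings (DESeq2's size factors, upper-quartile factors and library size only), no filter on low counts and a stricter one (a CPM of 1 in 8 libraries), DESeq2 1.42.0, limma voom with quality weights, the library number as a block, 2 surrogate variables (sva 3.50.0), removal of mitochondrial and rRNA genes, a minimum fold change of 2, a fit of the 2 groups compared alone, and each library left out in turn. Chosen after seeing the data were the fits without both LG/J libraries numbered 1, without 6 libraries holding transcripts of both sexes, without these 8 libraries, with close libraries of a group summed, and with the trend on gene length removed. The lists were also tested without LG/J male 6 and without SM/J female 2, which held the most macrophage transcripts of their groups. Near-identical copies of genes were searched with blastn 2.17.0 among annotated transcripts, at 95% identity over at least 150 bases and 50% of the shorter transcript, which covered 16034 of the 16136 genes kept (99.4%). This search first used 1 transcript per gene and was widened to all transcripts after known copies were missed. Other steps ran in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

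Reads from genes that overlap on opposite strands, and reads from near-identical copies, could have been counted for the wrong gene or for none. Intervals for counting error are not given, since PCR copies were not marked and the spread between libraries was far larger.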

Results

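RNA was sequenced from primary chondrocytes, the cells that build and maintain cartilage, taken from the femoral heads of mice at postnatal day 21 and cultured for 4 days. The mice belonged to the inbred strains LG/J, known for good healing of ear and cartilage wounds, and SM/J, known for poor healing. The study's question was which pathways go with regeneration and which with degeneration of cartilage. Each strain and sex gave 8 libraries, 32 in all. Total counts were 15840330 to 23610400 in LG/J females, 19602302 to 22523596 in LG/J males, 19760354 to 25571598 in SM/J females and 18556940 to 22864087 in SM/J males. Mitochondrial genes took 0.447 to 1.035% of counts. Nothing in the labels says that the 8 libraries of a group are separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

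The libraries carried a chondrocyte profile in every group. Col2a1, the main collagen of cartilage, averaged 9186 ± 4084 CPM in LG/J females, 9251 ± 3295 in LG/J males, 6954 ± 1670 in SM/J females and 9456 ± 1699 in SM/J males (SD, n = 8 each). Acan, which encodes the proteoglycan aggrecan, averaged 2185 ± 1138, 2088 ± 942.3, 1197 ± 587.6 and 1042 ± 261.5 CPM in the same order. Sox9, the transcription factor that specifies chondrocytes, averaged 479.4 ± 182.4, 432.7 ± 108.3, 310.7 ± 75.64 and 348.2 ± 32.78 CPM. Col1a1, the collagen of bone and fibrous tissue and a sign of lost chondrocyte character, averaged 745.1 ± 626.9, 387.9 ± 374.0, 1480 ± 1199 and 903.0 ± 571.6 CPM.

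Both LG/J libraries numbered 1 stood apart from the other 14 LG/J libraries. In the LG/J female numbered 1, Acan was at 48.21 CPM against 1177 to 3362 CPM in the other LG/J females, and in the LG/J male numbered 1 it was at 67.67 CPM against 1897 to 3249 CPM. Il6, an inflammatory cytokine, was at 63.87 and 39.77 CPM in these libraries and at most 0.6308 and 0.9612 CPM in the others of their groups. Spp1, which encodes the matrix protein osteopontin, was at 180500 and 164300 CPM against at most 10170 and 13430 CPM. Values without both libraries, a choice made after seeing the data, are given where a main result changed.

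Close pairs were also present. Over the 112 pairs of libraries within groups, the squared difference of a gene, as a median over genes and relative to that of sampling noise, had a median of 13.9 and reached 51.48. It was 3.71 to 4.44 in 6 pairs and 5.3 in the next pair, where sampling noise alone gives 1. The 6 pairs were LG/J females 4 and 5, LG/J females 7 and 8, LG/J males 2 and 3, LG/J males 4 and 5, SM/J females 3 and 4, and SM/J males 6 and 7. Each library counted as 1 replicate in the tests below, although these values cannot show whether close libraries came from separate cultures. Sex-linked transcripts, given below, bear on LG/J females 4 and 5 and SM/J females 3 and 4. Before TMM scaling, the Y-linked Ddx3y was at 23.52 and 20.27 CPM in the former pair and 81.04 and 84.51 CPM in the latter. In all other female libraries it was at most 1.34 CPM. That match argues against unrelated cells in these partners, but does not show whether they were separate wells. The other close pairs held no such mark. SM/J males 2 and 3, at 6.43 times sampling noise and so outside the 6 pairs, did share one. Before TMM scaling they held Xist at 16.79 and 15.24 CPM, against at most 0.41 CPM in the other SM/J males. They stayed separate libraries when the close pairs were summed. Values with each close pair summed to 1 library, also chosen after seeing the data, are given where a main call was lost.

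Sex-linked transcripts followed the labels in most libraries. Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503, GRCm38 chromosome X, 103460375 to 103483217), averaged 51.98 ± 10.69 CPM in LG/J females and 0.3216 ± 0.1443 CPM in LG/J males, and 43.44 ± 15.48 and 4.421 ± 7.766 CPM in SM/J females and males (SD, n = 8 each). Ddx3y, a Y-linked RNA helicase (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), averaged 5.733 ± 9.645, 167.7 ± 12.59, 20.67 ± 37.48 and 146.6 ± 28.87 CPM in the same order. In 6 libraries transcripts of both sexes were found together. Before TMM scaling, the libraries labelled LG/J female 4 and 5 held Ddx3y at 23.52 and 20.27 CPM beside Xist at 55.26 and 55.93 CPM. Those labelled SM/J female 3 and 4 held Ddx3y at 81.04 and 84.51 CPM beside Xist at 22.57 and 22.96 CPM. Those labelled SM/J male 2 and 3 held Xist at 16.79 and 15.24 CPM beside Ddx3y at 112.82 and 92.96 CPM. Directions between the sexes therefore rest on labels that these 6 libraries did not match fully.

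**Figure D1:**
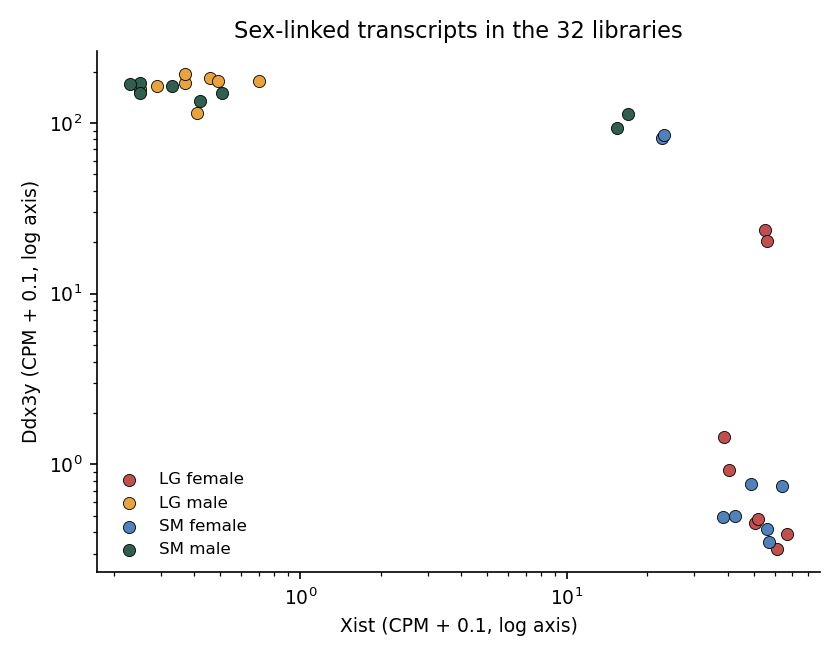
Xist against Ddx3y in each of the 32 libraries, in CPM plus 0.1 on log axes, colored by group (n = 8 each). Most libraries lie at high Xist and low Ddx3y or the reverse, and 6 libraries hold both, among them SM/J females 3 and 4 with Ddx3y at 81.04 and 84.51 CPM.

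Between the strains, the largest differences among genes with no near-identical annotated copy included those of Tnfrsf23, H2-Ab1, Traf3ip1 and Tmem87a. Tnfrsf23, a decoy receptor of the tumor necrosis factor receptor family (ENSMUSG00000037613, GRCm38 chromosome 7, 143665809 to 143685872), was 114-fold higher in LG/J, at 33.11 ± 16.96 against 0.2983 ± 0.2332 CPM (SD, n = 16 each; log2 fold change 6.83 ± 0.30, adjusted p = 1.75e-18). H2-Ab1, a chain of class II antigen-presenting molecules (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418), was 20.5-fold higher, at 40.0 ± 12.33 against 1.948 ± 1.897 CPM (4.35 ± 0.38, adjusted p = 7.5e-11). Traf3ip1, part of the transport machinery of cilia (ENSMUSG00000034292, chromosome 1, 91494647 to 91529307), was 14.7-fold lower in LG/J, at 4.439 ± 0.8574 against 65.86 ± 9.978 CPM (-3.88 ± 0.08, adjusted p = 4.03e-28). Tmem87a, which encodes a membrane protein of the Golgi (ENSMUSG00000033808, chromosome 2, 120355312 to 120404113), was 11.9-fold lower, at 9.656 ± 1.661 against 114.7 ± 8.183 CPM (-3.57 ± 0.07, adjusted p = 5.17e-29). All 16 LG/J libraries lay on 1 side of all 16 SM/J libraries for each of these genes.

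Further genes without an annotated copy that were higher in LG/J were Tmie, a part of the hair cell transduction channel (4.12 ± 0.32, adjusted p = 8.25e-12), Cramp1l (3.50 ± 0.05, adjusted p = 7.79e-32), Srbd1 (3.07 ± 0.09, adjusted p = 8.04e-24) and Lrp4. Lrp4, a cell-surface receptor that binds Wnt inhibitors (ENSMUSG00000027253, chromosome 2, 91457511 to 91513779), averaged 64.26 ± 45.72 against 6.119 ± 1.363 CPM (3.38 ± 0.31, adjusted p = 2.39e-10). Lower in LG/J were H2-T24, a class Ib histocompatibility gene (-4.03 ± 0.20, adjusted p = 4.94e-17), and Pdlim1, which binds the actin cytoskeleton (-3.51 ± 0.27, adjusted p = 2.59e-12). Of the 20 genes with the largest differences, 10 each way, the other 10 had near-identical annotated copies. Among them were Rps26 (5.63 ± 0.12), Ndufs5 (5.22 ± 0.13), Lyz1 (-6.70 ± 0.41) and Ifit3 (-4.21 ± 0.24). Summed with their copies, the log2 ratios of mean CPM were 0.74 for Rps26, -0.37 for Ndufs5, -0.09 for Vcp-rs, 3.55 for Rab5b, -1.41 for Lyz1, -0.43 for Rpl14, 0.05 for Tpm3-rs7, -2.35 for Ifit3, -0.83 for Rpl26 and -3.40 for Rpl35a. Tmie and Tmem87a overlap genes on the opposite strand, Als2cl at 8.846 CPM and Ganc at 25.638 CPM, and their reads could not be told apart without a strand setting.

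In all, 4826 of 16136 genes differed between the strains over both sexes, 2652 higher and 2174 lower in LG/J, and 1252 of them by 2-fold or more. For 423 called genes the strains did not overlap (220 higher, 203 lower). If all libraries are independent, chance separates 16 from 16 libraries for 3.33e-07 percent of genes. The labels do not show such independence and close pairs were present, so that percentage may not apply here. The number of strain differences over both sexes was 2634 with close libraries summed at a wider limit of 7 times sampling noise, which left 21 libraries. Of 131 strain calls among the genes named by rule, 119 were kept without both LG/J libraries numbered 1, 116 without the 6 libraries holding transcripts of both sexes, 116 with the close pairs summed and 97 at the wider limit.

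The genes that mark cartilage itself differed less. Prg4, the lubricin of the joint surface (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), averaged 1302 ± 1542 CPM in LG/J and 372.5 ± 182.0 CPM in SM/J (SD, n = 16 each; 1.83 ± 0.45, adjusted p = 0.00243), and 1.06 ± 0.35 without both LG/J libraries numbered 1. Its call was lost with voom (0.84, adjusted p = 0.074) and without both these and the 6 libraries with transcripts of both sexes (0.78, adjusted p = 0.186), in a range over all alternatives of 0.000674 to 0.186. Acan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099) averaged 2136 ± 1011 and 1119 ± 446.7 CPM (0.94 ± 0.35, adjusted p = 0.0443), and Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760) 456.0 ± 146.9 and 329.5 ± 59.55 CPM (0.47 ± 0.15, adjusted p = 0.0163). Col2a1, at 9219 ± 3585 and 8205 ± 2078 CPM, did not pass the test (0.19 ± 0.24, adjusted p = 0.613). Nor did the hypertrophy genes Col10a1 (1.12 ± 0.43, adjusted p = 0.0509) and Mmp13 (0.20 ± 0.36, adjusted p = 0.723), the aggrecanase Adamts5 (1.16 ± 0.59, adjusted p = 0.14) or Col1a1 (-1.10 ± 0.48, adjusted p = 0.0798). The Acan call was lost in 23 of the 32 fits that left out 1 library, with adjusted p up to 0.0718. It was kept without LG/J females 1, 3 or 6, LG/J male 1, SM/J females 5, 7 or 8, or SM/J males 1 or 4. The calls of Acan and Sox9 were lost with the close pairs summed (adjusted p = 0.198 and 0.105) and without the 6 libraries with transcripts of both sexes (0.222 and 0.145), in a range over all alternatives of 1.59e-05 to 0.418 for Acan and 1.85e-05 to 0.277 for Sox9. Without both LG/J libraries numbered 1, the log2 fold changes were 1.12 ± 0.18 for Acan (adjusted p = 1.59e-05), 0.59 ± 0.10 for Sox9 (1.85e-05), 0.36 ± 0.10 for Col2a1 (0.00758), 1.31 ± 0.32 for Col10a1 (0.00193), -0.56 for Mmp13 (0.0669) and -0.83 ± 0.26 for Adamts5 (0.0165). The sign thus turned for Mmp13 and Adamts5.

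**Figure D2:**
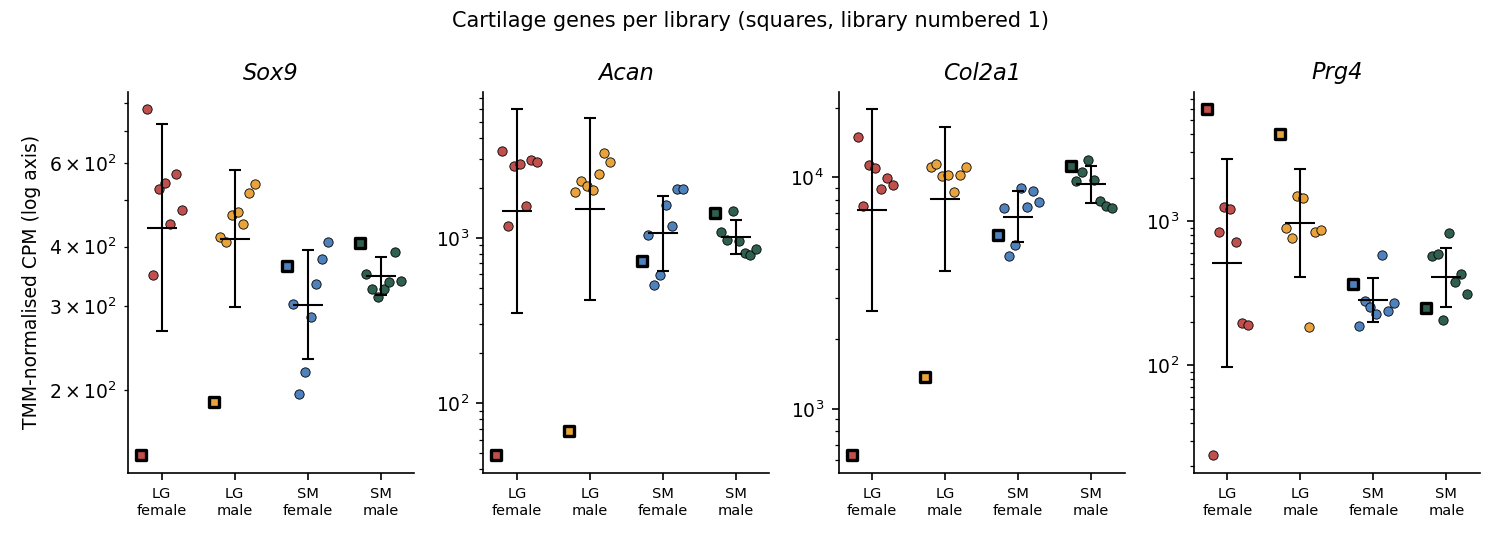
Sox9, Acan, Col2a1 and Prg4 in TMM-scaled CPM on a log axis, 1 point per library and 8 libraries per group, with squares for libraries numbered 1 and bars for the mean ± SD of log2 values. The LG/J libraries numbered 1 lie far below the others of their groups in Acan, at 48.21 and 67.67 CPM, and in Col2a1, at 629.3 and 1379 CPM.

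Of the 24 cartilage matrix genes, 3 were higher and 1 lower in LG/J (2 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.892). Besides Acan, the linker of aggrecan to hyaluronan Hapln1 was higher (1.00 ± 0.27, adjusted p = 0.00434), as was Chadl (0.83, adjusted p = 0.0148). The matrilin gene Matn4 was lower (-1.28, adjusted p = 0.00763). With the close pairs summed, Hapln1 (adjusted p = 0.0512) and Chadl (0.132) lost their calls, and over all alternatives the highest adjusted p was 0.187 and 0.369. Without both LG/J libraries numbered 1, 12 members were higher and 2 lower (16 and 2 over the list alone), and the list passed (adjusted p = 0.00259, but adjusted p = 0.691 with an estimated correlation). Of 11 superficial zone genes, Prg4 and Vit (0.64, adjusted p = 0.0345) were higher and Tspan15 lower (-1.04, adjusted p = 0.0203), with camera adjusted p = 0.892 and the same 2 and 1 adjusted over the list alone. Vit lost its call in 11 of the 32 fits without 1 library, with adjusted p up to 0.0793, namely without LG/J females 4 or 5, LG/J males 4, 5, 7 or 8, SM/J females 3 or 4, or SM/J males 6, 7 or 8. Both Vit (0.495) and Tspan15 (0.109) lost it without the 6 libraries with transcripts of both sexes, and Vit with the close pairs summed (0.236), in ranges over all alternatives up to 0.561 and 0.149.

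Regulators of chondrocytes were higher in LG/J where they differed. Of 19, 9 were higher and none lower (10 and 0 over the list alone), among them Shox2, a homeobox gene of limb growth (1.09 ± 0.12, adjusted p = 4.74e-09), Trps1 (0.79 ± 0.10, adjusted p = 2.1e-07) and Hif1a, the oxygen-sensitive factor of growth plate cells (0.56 ± 0.10, adjusted p = 3.67e-05). Of 21 hypertrophy and mineralization genes, 8 were higher and none lower (13 and 0 over the list alone), led by the transcription factors Runx3 (0.98 ± 0.15, adjusted p = 5.27e-06), Mef2c (1.13 ± 0.19, adjusted p = 1.8e-05) and Runx2 (0.65 ± 0.12, adjusted p = 7.56e-05). Neither list passed camera (adjusted p = 0.0695 and 0.0831). Fry, which does not compare a list with other genes, passed them as higher (adjusted p = 6.52e-06 and 0.00163). The 22 genes of dedifferentiation gave 2 higher and 9 lower (2 and 10 over the list alone; camera adjusted p = 0.0695). Acta2, smooth muscle actin, was lower (-2.70 ± 0.47, adjusted p = 3.51e-05), as was the mesenchymal factor Twist1 (-0.81 ± 0.12, adjusted p = 3.93e-06). The surface marker Thy1 was higher at a low level, 0.6426 ± 0.3106 against 0.1032 ± 0.09683 CPM (2.57 ± 0.34, adjusted p = 4.31e-07). Shox2 and Runx2 overlap Rsrc1 and Supt3 on the opposite strand.

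Several proteases and protease inhibitors were lower in LG/J. Serpinh1, the chaperone of newly made collagen (ENSMUSG00000070436, chromosome 7, 99345375 to 99353230), was 5.01-fold lower in LG/J, at 2423 ± 820.8 against 12110 ± 2733 CPM (SD, n = 16 each; -2.32 ± 0.19, adjusted p = 1.52e-11), with no overlap between the strains. Timp2, an inhibitor of metalloproteases, averaged 170.9 ± 18.2 against 234.8 ± 41.49 CPM (-0.46 ± 0.07, adjusted p = 1.09e-05). Of the 16 genes of the inhibitor list 8 were lower and none higher (8 and 0 over the list alone), and the list passed camera (adjusted p = 0.000473, but adjusted p = 0.0864 with an estimated correlation). This list counts Serpinh1, although it is a collagen chaperone, and was not tested without it. Among 27 matrix proteases 8 were lower and 2 higher, likewise over the list alone. The lower ones included Adamts9 (-1.64 ± 0.16, adjusted p = 1.13e-09), the plasminogen activator Plau (-1.57 ± 0.30, adjusted p = 0.000157), the lysosomal protease Ctsl (-0.48, adjusted p = 0.000155) and the macrophage elastase Mmp12 (-3.18 ± 0.64, adjusted p = 0.000253). The higher ones were the stromelysins Mmp3 and Mmp10 (2.54 and 2.22, adjusted p = 0.0498 and 0.0479). Mmp3 was at 35070 and 27410 CPM in the LG/J libraries numbered 1 against at most 530.2 and 1038 CPM in the others of their groups. This list passed as lower (camera adjusted p = 0.0261, adjusted p = 0.794 with an estimated correlation), but not without the 6 libraries with transcripts of both sexes (0.117) or with the close pairs summed (0.0646). Of 19 markers of macrophages, which also make Mmp12, 7 were lower in LG/J as well (median -1.43, adjusted p = 0.794 with an estimated correlation).

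Signalling genes differed in both directions. Of 38 Wnt pathway genes, 13 were higher and 6 lower in LG/J (13 and 7 over the list alone; camera adjusted p = 0.268), among the higher ones the nuclear effectors Tcf7l2 (0.76 ± 0.06, adjusted p = 6.06e-12) and Lef1 (1.52 ± 0.18, adjusted p = 4.73e-08). The Wnt target Axin2 (-0.50 ± 0.23, adjusted p = 0.0999) and the ligand gene Wnt16 (-0.25, adjusted p = 0.653) did not pass, and Axin2 passed without both LG/J libraries numbered 1 (-0.66, adjusted p = 0.0255). Of 12 hedgehog pathway genes 4 were higher and none lower (4 and 0 over the list alone; camera adjusted p = 0.154), including the receptor Ptch1 (1.03 ± 0.16, adjusted p = 3.59e-06) and the effectors Gli3 (0.24, adjusted p = 0.0132) and Gli1 (1.51, adjusted p = 0.0153). Gli1 lost its call with the close pairs summed (0.12) and Gli3 with the length trend removed (0.247), in ranges over all alternatives up to 0.378 and 0.247. The TGF-beta and BMP pathway gave 11 higher and 7 lower of 43 (11 and 8 over the list alone; camera adjusted p = 0.9), with Bmp6 (1.72 ± 0.28, adjusted p = 1.31e-05) and Smad1 (0.42, adjusted p = 6.28e-05) higher and Id3 lower (-0.68, adjusted p = 0.000133). Of 25 FGF and IGF pathway genes 6 were higher and none lower (5 and 0 over the list alone; camera adjusted p = 0.749), led by the insulin receptor substrate Irs1 (1.29, adjusted p = 6.19e-08). Fgf10, also in that list, was called at 2.51 (adjusted p = 0.00801), but not without LG/J female 1 (0.101) or LG/J male 1 (0.0778), and was at 0.15 without both (adjusted p up to 0.962 over all alternatives).

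DNA repair genes differed in both directions. Ogg1, the glycosylase that removes oxidized guanine (ENSMUSG00000030271, chromosome 6, 113326972 to 113335068), averaged 28.24 ± 2.757 CPM in LG/J and 14.65 ± 1.559 CPM in SM/J with no overlap (SD, n = 16 each; 0.94 ± 0.06, adjusted p = 4e-15). It overlaps Camk1 on the opposite strand, which averaged 33.422 CPM before TMM scaling. The mismatch repair gene Msh3 (0.85 ± 0.11, adjusted p = 5.67e-07) and the end-joining gene Xrcc6 (0.32, adjusted p = 0.00025) were also higher, and the list of 60 gave 6 higher and 8 lower (likewise over the list alone; camera adjusted p = 0.894). Xrcc2 did not pass (0.13, adjusted p = 0.231). The replication clamp Pcna was lower by a small amount (-0.24 ± 0.09, adjusted p = 0.0395), a call lost in 12 of the 32 fits without 1 library (adjusted p up to 0.0743), namely LG/J females 1 or 5, LG/J males 4, 7 or 8, SM/J females 2, 3, 4 or 5, or SM/J males 6, 7 or 8. It was also lost without both LG/J libraries numbered 1 (0.0561), without the 6 libraries with transcripts of both sexes (0.101) and with the close pairs summed (0.187), in a range of 0.0292 to 0.395. Of 42 cell cycle genes 4 were lower, among them Cdt1 (-1.06, adjusted p = 0.00126) and Nusap1 (-0.85, adjusted p = 0.0104), and E2f2 was higher (0.75, adjusted p = 0.0063), with 1 higher and 2 lower over the list alone. Nusap1 lost its call with the close pairs summed (0.0812) and without the 6 libraries with transcripts of both sexes (0.157), in a range of 0.000513 to 0.17. Over all alternatives the adjusted p was at most 0.0747 for Cdt1, 0.0628 for Xrcc6 and 0.0666 for E2f2, each over 0.05 in 1 of 16. The list passed as lower (camera adjusted p = 0.0332, adjusted p = 0.961 with an estimated correlation), but not with the close pairs summed (0.193) or without SM/J female 2 (0.0555). Cdkn1a, an inhibitor of the cell cycle, did not pass (0.14, adjusted p = 0.596). The p53 and senescence list gave 1 higher and 6 lower of 25 (likewise over the list alone; camera adjusted p = 0.268), the apoptosis list 3 and 7 of 29 (3 and 8; 0.541) and the autophagy and lysosome list 1 and 6 of 34 (1 and 6; 0.154). Examples were the death-promoting Bmf (1.91, adjusted p = 7.53e-07) and the lysosomal sialidase Neu1 (-0.94, adjusted p = 2.71e-06). The p53 target Pmaip1 was also lower (-1.46, adjusted p = 0.00775), but not called in 3 of 16 alternatives (range 0.000165 to 0.11). These were the fit without the 6 libraries with transcripts of both sexes (0.0727), that without these and both LG/J libraries numbered 1 (0.11), and the wider limit (0.0915).

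Several respiratory chain genes were lower in LG/J by small amounts. Of 36 nuclear-encoded oxidative phosphorylation genes 17 were lower and none higher (18 and 1 over the list alone), with a median log2 fold change of -0.14, for example Ndufb10 of complex I (-0.38 ± 0.07, adjusted p = 2.75e-05) and Sdha of complex II (-0.27 ± 0.05, adjusted p = 2.92e-05). The list passed (camera adjusted p = 0.000473, adjusted p = 0.794 with an estimated correlation). Other metabolic genes gave larger single differences. Gsta4, which detoxifies lipid peroxidation products, averaged 3.166 ± 1.915 against 30.41 ± 16.02 CPM (SD, n = 16 each; -3.22 ± 0.30, adjusted p = 5.09e-10), among 2 higher and 6 lower of 36 antioxidant genes (likewise over the list alone; camera adjusted p = 0.073). Hyou1, a chaperone of the endoplasmic reticulum (ENSMUSG00000032115, chromosome 9, 44379490 to 44392369), averaged 207.2 ± 17.44 against 81.73 ± 22.72 CPM with no overlap (1.37 ± 0.08, adjusted p = 2.08e-15). The chaperone Canx was lower (-0.56, adjusted p = 5.48e-08), and the unfolded protein response list gave 3 higher and 4 lower of 25 (likewise over the list alone; camera adjusted p = 0.884). Of 25 glycolysis and hypoxia genes 8 were higher and 2 lower (likewise over the list alone; camera adjusted p = 0.171), among them the carbonic anhydrase Car12 (1.28 ± 0.13, adjusted p = 1.71e-09). Gapdh, counted as lower in that list (-0.67, adjusted p = 1.93e-06), has 95 near-identical annotated copies. Summed with these, its log2 ratio of mean CPM turned from -0.67 to 1.62. Dhcr7, an enzyme of cholesterol synthesis, was higher (1.28 ± 0.10, adjusted p = 6.97e-12). Its lipid list had 7 higher and 2 lower of 28 (7 and 4 over the list alone), a median of -0.07, a mean of 0.03 and camera adjusted p = 0.892 as lower.

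Immune genes within the lists differed in both directions. The interferon response list gave 3 higher and 8 lower of 31 in LG/J (likewise over the list alone; camera adjusted p = 0.0831), with Ifi35 (-1.62 ± 0.13, adjusted p = 1.06e-11) and Ifit2 (-1.86 ± 0.25, adjusted p = 7.44e-07) beside Ifit3, while 7 of 19 macrophage markers were lower (adjusted p = 0.794 with an estimated correlation). The interferon list passed as lower without LG/J male 6 (3 higher and 11 lower, likewise over the list alone; adjusted p = 0.0404, adjusted p = 0.862 with an estimated correlation). Of 20 antigen presentation genes 8 were higher and 5 lower (8 and 6 over the list alone; camera adjusted p = 0.53). The complement list gave 3 higher and 2 lower of 16 (likewise over the list alone; camera adjusted p = 0.642). Of 31 inflammatory cytokine genes 9 were higher and 1 lower (likewise over the list alone), with a median of 0.76 and a mean of 1.19 although camera ranked the list as lower (adjusted p = 0.485). Tnfrsf11b, which encodes osteoprotegerin, a decoy receptor that limits bone resorption, was lower (-1.20 ± 0.15, adjusted p = 9.28e-08). Il6 was called higher (4.05 ± 1.01, adjusted p = 0.00251), but not without the LG/J female numbered 1 (adjusted p = 0.0862), and it was at -0.10 (adjusted p = 0.893) without both LG/J libraries numbered 1. Without these the list gave 2 higher and 18 lower, a median of -0.87 and camera adjusted p = 0.00718 (adjusted p = 0.691 with an estimated correlation).

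Several markers of macrophages and monocytes were lower in LG/J, at low levels. Of 19 such markers 7 were lower and none higher over both sexes (10 and 0 over the list alone), with a median of -1.43, and the list passed (camera adjusted p = 0.000473, adjusted p = 0.794 with an estimated correlation). Ccr2, a chemokine receptor of monocytes (-2.53 ± 0.58, adjusted p = 0.00107), the pore-forming Mpeg1 (-3.04 ± 0.72, adjusted p = 0.00148) and the antibody receptor Fcgr1 (-2.68 ± 0.68, adjusted p = 0.00313) led the list. Lyz2, a lysozyme of macrophages, averaged 95.22 CPM in LG/J and 214.1 CPM in SM/J. Mpeg1 was at 12.59 CPM in LG/J male 6 and at no more than 0.49 CPM in the other 15 LG/J libraries, and at 25.77 CPM in SM/J female 2. The median of the 19 markers was 47.5 CPM in LG/J male 6, 0.33 to 5.6 CPM in the other LG/J libraries, 48.7 CPM in SM/J female 2 and 0.841 to 25.6 CPM in the other SM/J libraries. Without LG/J male 6, 15 markers were lower (16 over the list alone; median -2.67, camera adjusted p = 3.63e-06, adjusted p = 0.775 with an estimated correlation), and without SM/J female 2, 4 (4; -0.99, 0.00198, 0.753). Of 8 osteoclast markers 3 were lower (3 over the list alone; camera adjusted p = 0.155), Oscar (-2.37, adjusted p = 6.94e-07), Dcstamp (-2.76, adjusted p = 5.08e-06) and Atp6v0d2 (-1.66, adjusted p = 0.00266). Atp6v0d2 was not called at the wider limit (0.117).

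Among signs of RNA quality, 2 of 7 mitochondrially encoded genes were higher in LG/J (2 over the list alone; camera adjusted p = 0.892), 3 of 35 ribosomal protein genes were higher and 5 lower (likewise over the list alone; 0.154), and 4 of 14 heat shock genes were lower (4 over the list alone; 0.0695). The lower ribosomal protein genes included Rpsa and Rplp0, which have near-identical annotated copies. Summed with these, the log2 ratios of mean CPM went from -1.86 to -1.32 for Rpsa and from -1.24 to -0.64 for Rplp0. The heat shock genes included Hsph1 (-0.48, adjusted p = 0.000374) and Bag3 (-0.45, adjusted p = 0.000941), the latter not called at the wider limit (0.0534). The mitochondrially encoded genes, mt-Nd4 (0.34) and mt-Nd5 (0.31), lost their calls without both LG/J libraries numbered 1 (adjusted p = 0.0787 and 0.122) and in 16 and 14 of the 32 fits without 1 library, with adjusted p up to 0.0806 and 0.0758. Of 19 immediate early genes 1 was higher and 1 lower (0 and 1 over the list alone; camera adjusted p = 0.892).

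Strain differences in females and males were correlated across genes. In females 2156 genes differed (1109 higher, 1047 lower in LG/J) and in males 3600 (2070 higher, 1530 lower), of which 1573 were shared, against 481 for independent lists. Of the shared genes 877 were higher and 694 lower in both sexes, and 2 were opposite. Across all 16136 genes, which are not independent replicates, the log2 fold changes of females and males, which share no library, had Pearson's r = 0.803 and Spearman's rho = 0.644. Without a filter on low counts r was 0.442. They had the same sign for 92.04% of genes called in either sex. Tnfrsf23 was higher by 6.55 in females and 7.12 in males, and Serpinh1 lower with -2.39 and -2.26. The macrophage and monocyte list was lower in females, with 12 of 19 members lower and none higher (15 and 0 over the list alone), a median of -3.46 and camera adjusted p = 2.4e-05 (adjusted p = 0.866 with an estimated correlation). In males none of its members passed the edgeR test over all genes or over the list alone, with a median of 0.09 and camera adjusted p = 0.0716 as lower. Without LG/J male 6, however, 7 were lower in males and none higher (9 and 0 over the list alone), with a median of -1.75 and camera adjusted p = 0.000372 (adjusted p = 0.889 with an estimated correlation). Whether a list's strain difference differed between the sexes was not tested, here or for the lists that follow. Of 36 oxidative phosphorylation genes 21 were lower and 1 higher in males (24 and 1 over the list alone; camera adjusted p = 2.45e-06, adjusted p = 0.911 with an estimated correlation), and 6 lower and 1 higher in females (9 and 1; 0.286). Ribosomal RNA took 0.654 to 0.956% of counts in LG/J males. It took 0.367 to 0.48% in SM/J males 3 to 8, and 0.969 and 0.698% in SM/J males 1 and 2. Across autosomal genes the strain effect over both sexes correlated with gene length at rho = 0.15. Whether a difference in library preparation adds to the strain differences in males was not tested.

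The ribosomal protein list, a sign of RNA quality, also passed as lower in males, with 4 of 35 lower and 1 higher (likewise over the list alone), a median of -0.09 and camera adjusted p = 0.0307 (adjusted p = 0.911 with an estimated correlation). It did not pass without LG/J male 6 (0.121), nor in females (4 lower and 2 higher, likewise over the list alone; median 0.07, camera adjusted p = 0.552). Its members Rpsa and Rplp0 have near-identical annotated copies, and their strain differences over both sexes were smaller when summed with these. Whether reads assigned to copies shaped this list's result was not tested. The interferon response list passed as lower in females, with 8 of 31 lower and 1 higher (11 and 1 over the list alone), a median of -0.55 and camera adjusted p = 0.00932 (adjusted p = 0.961 with an estimated correlation). Without SM/J female 2 it did not pass there (5 lower and 1 higher, likewise over the list alone; median -0.21, adjusted p = 0.142). In males it gave 3 higher and 3 lower (likewise over the list alone) and a median of 0.31 although camera ranked it as lower (adjusted p = 0.516). The protease inhibitor list, which includes Serpinh1, passed as lower in both sexes, with 4 of 16 in females and 5 in males (5 and 7 over the list alone) and none higher. Its camera adjusted p was 0.00202 and 0.00165 (adjusted p = 0.187 and 0.169 with an estimated correlation). Matrix proteases passed as lower in females (6 of 27, 7 over the list alone; camera adjusted p = 0.0113, adjusted p = 0.618 with an estimated correlation) and not in males (3 of 27, likewise over the list alone; 0.108), with none higher in either.

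**Figure D3:**
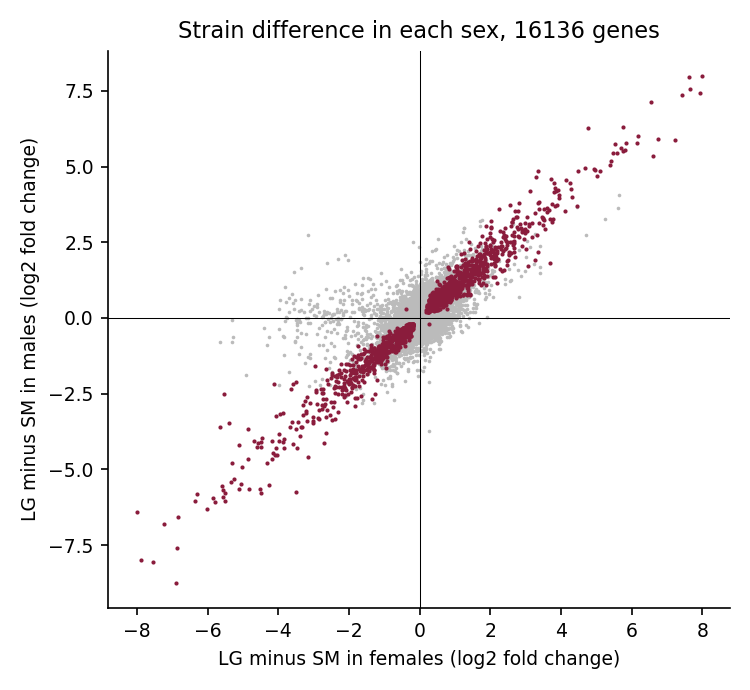
Log2 fold change LG/J minus SM/J in females (horizontal) and males (vertical) for 16136 genes, with the 1573 genes called in both sexes in dark red. Most points lie along the diagonal (r = 0.803).

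A test of the difference itself called 1 gene in edgeR, against 55 with DESeq2, 256 with voom and 118 with 2 surrogate variables. Med1, a subunit of the Mediator complex that links transcription factors to RNA polymerase (ENSMUSG00000018160, chromosome 11, 98152154 to 98193293), averaged 291.1 ± 16.38 and 278.3 ± 26.41 CPM in LG/J females and males and 241.7 ± 14.68 and 323.1 ± 19.88 CPM in SM/J females and males (SD, n = 8 each). Its strain difference was 0.27 ± 0.06 in females and -0.22 ± 0.06 in males, which differed by -0.48 ± 0.08 (adjusted p = 0.0331), and 1345 genes had an unadjusted p under 0.05. The call was lost in 25 of the 32 fits without 1 library, with adjusted p up to 0.145, and was kept without LG/J female 1, LG/J male 8, SM/J females 1 or 5, or SM/J males 1, 2 or 6. The number of genes called was 22 without LG/J male 8, 23 without SM/J male 1, 2 without SM/J female 5 or SM/J male 2, and 0 in edgeR without 1 of the 25 libraries whose removal ended the Med1 call. Over the other alternatives the adjusted p of Med1 ran from 1.65e-05 to 1, with 0.597 for the close pairs summed.

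Between the sexes, the genes that differed in both strains together included Phactr2 and sex-linked genes. Phactr2, which binds actin and protein phosphatase (ENSMUSG00000062866, chromosome 10, 13207717 to 13474396), was higher in males, at 26.92 ± 15.56 against 18.53 ± 5.966 CPM in LG/J and 70.48 ± 29.72 against 16.83 ± 3.042 CPM in SM/J (SD, n = 8 each; 1.30 ± 0.20, adjusted p = 0.000661). Within strains it was called in SM/J (2.07 ± 0.29, adjusted p = 0.000145) and not in LG/J (0.54 ± 0.28, adjusted p = 0.883), and the difference between them did not pass (-1.53, adjusted p = 0.215). Among LG/J males its log2 CPM (prior count 2) was 6.013 in male 8 and at most 4.74 in the others, so that library raised their mean. Other autosomal genes higher in males were Mettl7a1 (0.63), Dmtn (0.60), Agbl2 (0.52) and the long noncoding RNA Bvht (0.50). Those lower in males were the p53 target Perp (-1.96 ± 0.48), Lurap1l (-1.61), the collagen receptor Itga2 (-1.32), Ptprv (-1.27) and Ano3 (-1.20), with adjusted p of 0.0134 to 0.0432 over these 9 genes. All 9 lost their calls with the close pairs summed (adjusted p = 0.0918 to 0.159; up to 0.475, for Itga2, over all alternatives), while Phactr2 kept its call (0.0251) but not at the wider limit (0.12). In fits without 1 library Agbl2 lost its call in 23 of 32, Ptprv in 16 and Itga2 in 14, each with its highest adjusted p (0.0835, 0.09 and 0.0865) without SM/J female 3. Bvht lost it without SM/J female 4 or SM/J male 5 (adjusted p up to 0.0505).

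Over both strains 558 genes differed between the sexes, 215 higher and 343 lower in males, and 510 of them were autosomal (202 and 308). Of the X-linked genes known to escape inactivation 7 of 8 were lower in males (8 over the list alone), among them Xist (-5.31 ± 0.58, adjusted p = 2.18e-06), Kdm6a (-0.94 ± 0.10, adjusted p = 2.01e-06) and Kdm5c (-0.61, adjusted p = 0.000154). The list passed (camera adjusted p = 5.49e-19, adjusted p = 0.000261 with an estimated correlation). The Y-linked genes Ddx3y (3.84 ± 0.78, adjusted p = 0.00858), Uty (3.50, adjusted p = 0.00548), Kdm5d (3.49, adjusted p = 0.00476) and Eif2s3y (3.87, adjusted p = 0.00476) were higher in males. Without the 6 libraries with transcripts of both sexes, Xist was at -7.52 and Ddx3y at 8.35. At the wider limit the 4 Y-linked genes lost their calls (adjusted p = 0.187 for Ddx3y and 0.181 for the others). Of 36 oxidative phosphorylation genes 11 were higher and 2 lower in males (18 and 3 over the list alone; camera adjusted p = 3.59e-08, adjusted p = 0.978 with an estimated correlation), with Ndufa1 (0.25, adjusted p = 0.00476) and Ndufb5 (0.27, adjusted p = 0.0163) higher and Cyc1 lower (-0.84, adjusted p = 0.0129). Scaled by library size only, that list gave none higher and 2 lower, with a median of 0.08. With the close pairs summed no member was called over all genes, against 11 higher and 2 lower over the list alone. Camera also passed ribosomal protein genes as higher, with 1 of 35 members called (1 over the list alone; adjusted p = 1.93e-06, adjusted p = 0.978 with an estimated correlation). The cartilage matrix list held no gene called by edgeR over all genes or over the list alone, and did not pass (camera adjusted p = 0.112). Higher calls made up 38.5% of the 558, and 3.98% with library size only.

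The count over both strains was far from stable. It was 922 without both LG/J libraries numbered 1, 31 with the close pairs summed and 7 at the wider limit. Leaving out 1 library gave 963 without LG/J male 1 and 904 without SM/J male 1, but 360 without LG/J female 3, 367 without LG/J male 5, 314 without LG/J male 8, 321 and 355 without SM/J females 3 and 4, and 364, 360, 357 and 365 without SM/J males 4, 5, 6 and 7.

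Within SM/J 929 genes differed between the sexes, 371 higher and 558 lower in males, and 876 were autosomal (352 and 524). Of these 44 differed by 2-fold or more. Ribosomal RNA took 0.367 to 0.48% of counts in SM/J males 3 to 8, 0.969 and 0.698% in SM/J males 1 and 2, and 0.66 to 0.904% in SM/J females. The autosomal genes higher in males had a median length of 1742 bases and the lower ones 6094 bases, against 3505 bases over all genes. Of 36 oxidative phosphorylation genes 16 were higher and 2 lower (22 and 2 over the list alone; camera adjusted p = 7.32e-11, adjusted p = 0.699 with an estimated correlation). Camera also passed ribosomal protein and antioxidant genes as higher (1 of 35 and 2 of 36 called, the same over each list alone; adjusted p = 4.39e-07 and 0.0253, adjusted p = 0.993 with an estimated correlation for both). Higher calls were 39.9% of all, 53.1% with upper-quartile factors and 9.23% with library size only. The count was 490 without the 6 libraries with transcripts of both sexes, 184 with the close pairs summed and 0 in edgeR at the wider limit, where 1338 genes had an unadjusted p under 0.05. Without SM/J male 1 it was 1410, and without SM/J females 3 or 4 or SM/J males 4, 5, 6 or 7 it was 587, 596, 575, 600, 542 and 532.

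Within LG/J 8 genes differed between the sexes, all on X or Y. Lower in males were Xist (-7.32 ± 0.92, adjusted p = 0.000121), Kdm6a (-0.85, adjusted p = 0.00518), Eif2s3x (-0.63, adjusted p = 0.0238), Pbdc1 (-0.54, adjusted p = 0.0299), 5530601H04Rik (-0.60, adjusted p = 0.0238) and Zfp711, and higher were Emd and the predicted Y-linked gene Gm29650. Ddx3y, at 4.86 ± 1.16, did not pass (adjusted p = 0.251), and LG/J females 4 and 5 held its transcript. Macrophage and monocyte markers had a median of 2.70 in LG/J males over females, with camera adjusted p = 4.02e-06 (adjusted p = 0.763 with an estimated correlation); no member was called over all genes, against 15 higher over the list alone. Without LG/J male 6 the median was 0.59, no member was called by edgeR over all genes or the list alone, and the list did not pass (0.0986). The count of 8 fell to 4 without LG/J female 4 or LG/J males 1, 3 or 6, and to 5 without LG/J females 2, 3, 5, 7 or 8 or LG/J males 2, 5, 7 or 8. Among the 876 autosomal genes called in SM/J, 694 (79.2%) had the same sign in LG/J, and across autosomal genes the sex effects of the strains had r = 0.138 and rho = 0.283.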

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

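The tests of a mislabelled strain over all separating genes and of close libraries counted as separate replicates were chosen before their results were seen, and all other tests in this part after. A library was singled out where its gap to the nearest of the other 7 in its group took an unusually large share of the group's range. This held in 33 of 244 groups of 8 values (56 genes and 5 library measures), where chance gives about 12.2, and 22 of the 33 lay in the LG/J libraries numbered 1.

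In the LG/J female numbered 1, the gap took 0.934 of the range for the share of counts in the top 10 genes (36.15% against 13.41% in the next), 0.753 for Acan, 0.785 for Col2a1, 0.796 for Col10a1, 0.606 for Mmp13, 0.779 for Adamts5, 0.586 for Rpl26, 0.584 for Eif2s3x, 0.585 for Utp14a and 0.565 for Pbdc1. In the LG/J male numbered 1 it took 0.908 for that share of counts (34.99% against 13.54%), 0.735 for Sox9, 0.861 for Acan, 0.867 for Col2a1, 0.767 for Col10a1, 0.581 for Adamts5, 0.655 for Srbd1, 0.683 for Rpl26, 0.579 for Mettl7a1, 0.638 for Uty, 0.575 for Ddx3x and 0.708 for Utp14a. These libraries were the highest of their groups in the share of counts, Mmp13 and Adamts5, and the lowest in the other genes.

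A few genes taking most of the counts are argued against as the whole cause, since the cartilage matrix list stayed at a median of -4.31 against the other LG/J libraries after TMM scaling (quartiles -5.48 to -2.67). Macrophages in the wells are argued against by their marker list, at -0.36 (quartiles -1.75 to 0.36), although the bound for that test was changed after the value was seen. A mislabelled strain was to be excluded at 90% of the genes that separate the strains, and of 502 such genes 83.5% placed the female and 83.3% the male library with LG/J, which missed that bound; among 31 genes at least 32-fold apart, chosen after, 100% did, which argues against it. An inflamed or stressed culture remains a possible explanation that was not tested, and no group of the design separates these libraries from the rest. By the same measure the inflammatory cytokine list was at 5.04 (quartiles 2.24 to 7.01), with 28 of 31 members at least 2-fold higher and 1 lower. Complement genes were at 1.58 (0.62 to 2.95) and immediate early genes at 1.28 (0.26 to 2.67). Heat shock genes were at -0.13 (-0.32 to 0.29) and unfolded protein response genes at -0.35 (-0.91 to -0.27).

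Other libraries stood apart in single values. LG/J female 2 had the fewest genes detected (0.554 of the range; 21214 against 24020) and the highest Kdm6a (0.578). LG/J male 6 was highest in H2-T24 (0.613) and Perp (0.536), LG/J male 8 in Phactr2 (0.684) and SM/J male 7 in Traf3ip1 (0.586). SM/J female 1 was lowest in Col10a1 (0.541) and SM/J male 8 in Axin2 (0.532). SM/J male 1 was lowest in Lurap1l (0.642), Utp14a (0.574) and Pbdc1 (0.65).

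Med1 was the gene whose strain difference differed between females and males by the test of that difference (adjusted p = 0.0331). Of 100 splits of the samples, the real one included, 6 gave at least 1 such gene and the highest other gave 698, so chance was not excluded, and splits with far more calls than the real one point to a structure of the samples.

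Strain differences of at least 8-fold were frequent among genes with a near-identical annotated copy: 71 of the 166 called genes had one (43.3% of those searched), against 10.4% of all searched genes. When these genes were summed with their copies, the median absolute log2 ratio went from 3.93 to 0.53 (quartiles 0.12 to 2.07), and 45 came to under 2-fold. Reads assigned to different copies in the 2 strains are a candidate explanation for that part, while 9 stayed at least 8-fold apart. For the 93 genes with no annotated copy, a strain variant that changes alignment and a difference in expression both stay open and were not tested.

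The sex difference within SM/J (929 genes) was more than in every other of 100 splits of these libraries (1 as large, the real one; highest other 9). With the close pairs kept together 2 of 100 splits gave as many as the real 184 (highest other 602), but at the wider limit edgeR called 0 (1338 at an unadjusted p under 0.05), so chance is excluded only as far as libraries beyond those pairs are independent. All these splits also counted genes on X and Y, which differ between the sexes in any case. Of the 929 genes 876 were autosomal, but the autosomal part of the 184 was not set against the splits. With the length trend removed 449 genes were called, 385 of them among the 929 (median absolute log2 fold change from 0.39 to 0.32, SE from 0.10 to 0.09). Without the libraries with markers of both sexes 490 were called. These counts argue against gene length bias or those libraries as the whole cause only if each library is independent. They were set against the splits of single libraries (highest other 9), and no splits were run in these 2 fits. Close libraries counted as separate replicates stay open as a candidate explanation that met its prediction. The prediction, set before the result, was fewer calls with the close pairs summed than in every fit leaving out as many other libraries per group. Summing the close pairs gave 184 calls, fewer than each of 59 such fits (317 to 2140, median 874). This test cannot decide whether the partners are dependent. The pairs were chosen as the closest in these same counts, and summing them removes the smallest differences within groups. All 59 fits left out only libraries outside the pairs and so kept each pair as separate replicates. What share of the calls close libraries account for was not tested. A biological difference between the sexes also stays open, as does a difference in library preparation, since ribosomal RNA took 0.367 to 0.48% of counts in SM/J males 3 to 8 against 0.66 to 0.904% in SM/J females, and neither was tested.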

How the results depend on the processing

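The fits without libraries, with libraries summed or with the length trend removed were chosen after seeing the data. The number of strain differences stayed within 1.5 times its value in 15 of 17 alternatives over both sexes (4826) and in 15 of 18 in each sex, and in all 32 fits without 1 library (4493 to 5151 over both sexes, 1886 to 2375 in females, 3008 to 4073 in males). The sex counts were less stable, within 1.5 times in 9 of 18 alternatives in LG/J, 8 of 18 in SM/J and 6 of 17 over both strains. Leaving out 1 library gave 4 to 9 genes in LG/J, 532 to 1410 in SM/J, 314 to 963 over both strains and 0 to 23 for the difference of strain effects between sexes. The correlation of strain effects ran from 0.736 to 0.866 and Mmp13 from -0.23 to 0.28. The effect of depth, at 15840330 to 25571598 counts per library, was not tested.

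A minimum fold change of 2 left 1252 strain differences over both sexes, 985 in females and 1108 in males, and 3, 44 and 32 sex differences in LG/J, SM/J and both strains, by its own construction. With close libraries summed at the wider limit the counts were 2634, 1276 and 1236 for strain and 1, 0 and 7 for sex, and with the close pairs summed 3, 184 and 31 for sex, in fits with fewer libraries. In the sex comparison within SM/J the 0 is edgeR's, with 1338 genes at an unadjusted p under 0.05. For the other moved values the cause was not tested. Females gave 3352 strain differences with 2 surrogate variables, and males 5636 with voom.

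For the sexes in LG/J, library size only gave 4 genes, DESeq2 20, voom 14, a fit of both groups alone 5, the fit without those 8 libraries 31 and the length trend removed 5. In SM/J, no filter gave 388, voom 2422, the block 1433, surrogate variables 2168, the fit without LG/J libraries numbered 1 1402, that without the 6 libraries with both sexes' transcripts 490, and the length trend removed 449. Over both strains these were 123 without a filter, 1029 with DESeq2, 1734 with voom, 1052 with the block, 1258 with surrogate variables, 922 without LG/J libraries numbered 1, 973 without those 8 libraries and 244 with the length trend removed.

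For the difference of strain effects between sexes, DESeq2 called 55 genes, voom 256 and surrogate variables 118. A minimum fold change of 2 gave 0, and edgeR gave 0 with library size only, no filter, the block, without the 6 libraries, without those 8, with pairs summed, at the wider limit and with the length trend removed. At an unadjusted p under 0.05 these 8 fits had 1136, 2443, 1513, 1973, 2739, 916, 584 and 1086 genes. The correlation of strain effects (0.803) was 0.878 for genes with a log2 CPM of at least 3, 0.442 with no filter, 0.710 without the 6 libraries and 0.646 without those 8. Of the list tests, 10 passed, against 1 with an estimated correlation, 20 with fry and 17 without LG/J libraries numbered 1. Between the strains fry passed lists that camera did not. Among them were osteoclast markers (fry adjusted p = 1.34e-05) and Wnt (0.000345), heat shock (0.000544) and hedgehog genes (0.00551). Cell cycle genes passed camera and not fry (0.258).

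The library number as a replicate block did not pair the samples by the criterion that all 8 numbers correlate above 0.1: this held for 4 to 7 of 8 numbers in the 6 pairs of groups, with 7 for LG/J females with LG/J males, r from -0.59 to 0.91, and a best match of 0 to 2 of 8 numbers. The block gave 1433 sex differences in SM/J, 1052 over both strains and 0 genes for the difference of strain effects.

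The sign of the strain difference turned for 5 genes, and of these values those of Adamts5 with DESeq2 (adjusted p = 0.00583) and without LG/J libraries numbered 1 (0.0165) were called. Adamts5 (1.16) was at -0.77 with DESeq2, -0.50 with voom, -0.32 with the block, -0.16 with surrogate variables, -0.83 without LG/J libraries numbered 1 and -0.42 without those 8. Mmp13 (0.20) was at -0.57 with voom, -0.39 with the block, -0.15 with surrogate variables, -0.56 without both LG/J libraries numbered 1, -0.28 without those 8, -0.14 without LG/J female 1 and -0.23 without LG/J male 1. Col2a1 was at -0.05 with surrogate variables, and Il6 at -0.14 with DESeq2 and -0.10 without LG/J libraries numbered 1. Xist (-1.74) was at 0.24 without the 6 libraries (adjusted p = 0.384) and 0.21 without those 8. Before TMM scaling it was at 16.79 and 15.24 CPM in SM/J males 2 and 3, which are among the 6. In the other SM/J males it was at most 0.41 CPM, so the main value of Xist rested on those libraries. For the other genes the cause was not tested beyond these fits.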

Other observations

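The splits of the samples given in this part were chosen after the results were seen. The neutrophil, endothelial, osteoblast, adipocyte, tendon, muscle, pericyte, neural, nuclear-retained, X-escape and sex steroid lists did not pass camera between the strains, although single members differed. Of 5 neutrophil genes 2 were lower in LG/J, Ngp (-2.37 ± 0.57, adjusted p = 0.00193) and Ltf (-2.52 ± 0.64, adjusted p = 0.00287), with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.268). Of 9 endothelial markers 1 was lower, Eng, which overlaps Ak1 on the same strand (-0.65 ± 0.10, adjusted p = 2.95e-06; 1 over the list alone; 0.581). Osteoblast and osteocyte markers gave 1 higher and 2 lower of 11 (2 and 2; 0.88), among them the bone transcription factor Dlx5 (-0.58, adjusted p = 0.0022). Adipocyte markers gave 1 lower of 5, Pparg (-1.28, adjusted p = 0.0136; 1 over the list alone; 0.454), a call lost with the close pairs summed (0.0514), in a range of 0.00068 to 0.193. Tendon, ligament and synovium genes gave 3 higher and 2 lower of 11, likewise over the list alone, with a median of -0.17, a mean of 0.39 and camera adjusted p = 0.647 as lower. Among them Thbs4 was at 2.37 (adjusted p = 0.00414) and at 0.71 (adjusted p = 0.166) without both LG/J libraries numbered 1, in a range of 0.000196 to 0.849 over all alternatives. At the wider limit Ltf (adjusted p = 0.078) and Dlx5 (0.0521) were not called.

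Skeletal muscle genes gave 1 higher and 1 lower of 7 (likewise over the list alone; median 0.08, mean 0.01, camera adjusted p = 0.892 as lower) and pericyte and smooth muscle genes 2 and 2 of 10 (likewise; median 0.25, mean -0.08, 0.892 as lower). Schwann and neural genes gave 2 higher of 7 (2 higher and 1 lower over the list alone; 0.794), including the myelin gene Mbp (1.09, adjusted p = 0.00147). Nuclear-retained RNAs, with Xist among them, gave 1 higher and 4 lower of 7 (likewise; 0.572), genes that escape X inactivation 3 and 2 of 8 (likewise; median 0.09, mean -0.13, 0.598 as higher), and sex steroid response genes 1 higher of 12, Gper1 (0.94, adjusted p = 0.00581; 1 over the list alone; 0.892). Mbp (adjusted p = 0.109) and Gper1 (0.0511) were not called at the wider limit. Xist, counted as lower in the nuclear-retained and X-escape lists, was at -1.74 (adjusted p = 0.015). Without the 6 libraries with transcripts of both sexes it was at 0.24 (0.384).

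Over both strains, camera also passed antioxidant and macrophage genes as higher in males (adjusted p = 0.0321 for both, adjusted p = 0.978 with an estimated correlation), with 1 of 36 and 0 of 19 members called by edgeR, the same over each list alone. Within LG/J it passed interferon genes (median 0.43, adjusted p = 0.000521) and superficial zone genes (0.36, 0.00474) and ribosomal protein genes (0.12, 0.037) as higher in males, and mitochondrially encoded genes (-0.22, 0.0339) as lower, with no member of these 4 lists called by edgeR over all genes or the list alone. The nuclear-retained list passed as lower (0.00524) with a median of -0.11 and a mean of -1.10, and its 1 called member of 7, likewise over the list alone, was Xist. With an estimated correlation the adjusted p of these 5 lists was 0.806, 0.744, 0.809, 0.809 and 0.676. The ribosomal protein list passed in the same direction within SM/J and over both strains. Without LG/J male 6 the macrophage list over both strains (0.318) and the interferon (0.121), mitochondrially encoded (0.197) and nuclear-retained (0.0676) lists within LG/J did not pass.

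Chance was excluded for the strain differences if each library is independent, since 1 of 100 splits, the real one, gave as many genes over both sexes (4826; highest other 975), in females (2156; 855) and in males (3600; 899). For the sex difference over both strains 2 of 100 gave as many (558, highest other 1081). The splits counted genes on X and Y as well as autosomal genes. For the sex difference within LG/J 14 of 100 gave at least 8 genes (highest other 2337), so chance was not excluded, and splits with many more calls than the real one point to a structure of these libraries.

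Since close libraries may not be independent, the splits were repeated with each close pair summed and so never parted, in 26 libraries. SM/J males 2 and 3, which shared Xist transcripts, stayed separate libraries there. The real split alone, 1 of 100, gave as many strain differences over both sexes (3604; highest other 27), in females (1527; 1) and in males (2447; 921), and as many sex differences over both strains (31; 1). Within SM/J 2 of 100 gave as many (184; highest other 602), and within LG/J 5 of 100 (3; 1006), where chance was not excluded. Chance is thus excluded for the other 5 counts only as far as libraries beyond these pairs are independent. The sex counts also held genes on X and Y, which differ between the sexes in any case. For autosomal genes alone these splits therefore cannot exclude chance. Xist, Kdm6a, Kdm5c, Eif2s3x and Y-linked genes were among the 31 calls over both strains. At the wider limit edgeR called 7 sex differences over both strains, with Xist, Kdm6a, Kdm5c and Eif2s3x among them. Within SM/J it called 0 there, where 1338 genes had an unadjusted p under 0.05.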
